A study of Mus musculus with 6 samples.

How the data were processed

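Messenger RNA was sequenced from whole liver of male C57BL/6 mice, 8 weeks old, after partial hepatectomy, the surgical removal of part of the liver, after which the remaining tissue grows back. Per the labels, the knockout groups lacked in hepatocytes either OGT, the enzyme that attaches the sugar O-GlcNAc to proteins, or OGA, the enzyme that takes it off. Per the labels, RNA of 3 mice was pooled in equal amounts for each group, each pool was run in 2 lanes, with a target of 25 M reads. The series gave 6 libraries in 6 groups: OGA-KO and OGA control at 14 days, the same pair at 28 days, and OGT-KO and OGT control at 28 days. An OGT pair at 14 days was not analysed here.

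The deposited count table held raw counts per Ensembl gene, as whole numbers, with both lanes already combined in 1 column per library. The deposited normalised table held CPM, the count scaled by the column total, without a composition factor. In the OGA columns each CPM value was the count divided by the column total. In the OGT columns the divisor was larger than the column total, which placed 158367 counts of the OGT-KO library (0.769%) and 22723 counts of the OGT control library (0.104%) outside the rows of the table. The submitters' processing notes name STAR, Subread and edgeR and the genome build mm39, without versions or settings. The tables gave no coordinates, and the annotation used here was of another build, so that it served only to give symbols to 12019 of the 12027 identifiers; no positions are given.

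The filter behind the 12027 rows was not stated. Every row held at least 28 counts summed over the 4 OGA libraries, while 56 rows held 0 counts in both OGT libraries. Genes expressed mainly in the OGT libraries therefore had less chance of a row, and genes without a row were not analysed here. The library totals ranged from 20433100 to 29327722 counts. A count of 0 allowed up to 3 counts, or 0.107 to 0.13 CPM.

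Each comparison of 2 libraries used the log2 ratio of CPM with TMM effective library sizes (edgeR 4.0.16, R 4.3.3) and a prior count of 2. The 95% interval of each ratio was the exact Clopper-Pearson interval of the conditional binomial share. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 library per group there was no check against replicates, and differences between mice were averaged within a pool. A size rule counted genes with at least a 2-fold difference and at least 1 CPM in the higher library. Against a library at 0, folds were computed against a floor of 3 counts per library and written as lower bounds.

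The main test fitted all 6 libraries together. The edgeR quasi-likelihood fit had 5 coefficients (intercept, line, day, OGA-KO and OGT-KO) and 1 residual degree of freedom, used filterByExpr (12026 genes tested) and took Benjamini-Hochberg adjusted p under 0.05 as its threshold. Its spread came from the difference of the OGA-KO effect between the times. The lone OGT libraries were assumed to vary like the OGA libraries. The words rose, fell and changed are kept for genes past this test. The test gave 1 OGA-KO effect as a mean over both times, 1 OGT-KO effect, and the contrast between these effects.

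For 42 gene lists on liver functions, cell types and stress responses, the median log2 ratio was placed among the medians of 10000 random lists of the same size and expression decile. A list stood apart below percentile 2.5 or above percentile 97.5, as a description of these libraries. Members needed at least 1 CPM in 1 library, and 40 lists had enough members. They also needed a row, which 18 of 30 listed mitosis, 13 of 20 cholangiocyte and 9 of 21 female-biased genes had. So had 9 of 17 recruited macrophage, 7 of 16 fetal and 4 of 12 neutrophil genes. List counts given below are of members with a row. The T and NK cell list and the B and plasma cell list, with 1 row each, were not scored. The genes named were Ogt and Oga; the 8 highest and 8 lowest ratios of OGT-KO, and of OGA-KO by the smaller of both times, at 10 CPM or more; the 5 highest and 5 lowest of the other comparisons; the 5 most abundant genes past the size rule each way in OGT-KO; up to 4 members of each list with the largest ratios; and a fixed set of liver and cell cycle genes. Predicted genes and clone names were passed over. Lists, comparisons, tests and this rule were set before the data were examined; any gene outside the rule is said to be chosen after its values were seen.

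The procedure was tested on simulated data with known changes. For OGA-KO, the edgeR fit recovered 2.99% of genes changed by 1.5-fold, 65.7% at 2-fold and 98.5% at 4-fold, and 9.02% of its calls were unchanged genes. For OGT-KO it recovered 1.49%, 11.9% and 84.8% at these folds, with 14.5% of calls unchanged genes. The size rule for OGT-KO passed 98.5% of 4-fold changes and 0.651% of unchanged genes. The counting interval covered a true ratio of 1 for 95.3% of genes. These simulations held no difference between pools beyond the fitted spread. For OGT-KO they changed 67, 67 and 66 genes at the 3 folds, whereas the fit to the data called 6332 genes. The shares given for the OGT-KO fit therefore describe sparse changes and not a difference as broad as the one in the data.

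Alternatives were library totals, DESeq2 size factors, the authors' CPM, prior counts of 0.5 and 10, no filter, a filter of 5 CPM, a counting interval beyond 1.5-fold, the DESeq2 1.42.0 Wald test, limma 3.58.1 with trend, and edgeR fits to the 4 OGA libraries alone, without the day term, or without 1 library. Fits without the line term, and counts without pancreas and clock genes or without the 20 Mup genes, were added after the data were seen. Lanes could not be analysed singly.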

Results

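The data comprised 6 libraries of liver mRNA, 1 per group, each from the pooled RNA of 3 mice. Total counts were 29327722 for OGA-KO and 26504375 for its control at 14 days, 27471275 for OGA-KO and 28971784 for its control at 28 days, and 20433100 for OGT-KO and 21852873 for its control at 28 days. No group had replicate libraries, so no difference could be set against a spread between replicates, and all ranges given after a log2 ratio are 95% counting intervals. Across genes, which are not independent replicates, Pearson's r of log2 CPM lay between 0.979 and 0.993 among the OGA libraries and between 0.94 and 0.951 for OGT control with these. For OGT-KO, r was 0.855 with its own control and 0.777 to 0.793 with the OGA libraries.

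Oga (ENSMUSG00000025220) was depleted in both OGA-KO libraries. It had 282 counts in OGA-KO and 1525 in control at 14 days (10.4 and 62.2 CPM, log2 ratio -2.57, -2.77 to -2.39) and 317 and 1760 counts at 28 days (12.8 and 67.2 CPM, log2 -2.38, -2.57 to -2.22). Ogt (ENSMUSG00000034160) had 2051 and 1798 counts in the OGA-KO and control pair at 14 days and 1964 and 2021 at 28 days. In OGT-KO, Ogt had 1205 counts against 1339 in control (log2 -0.43, -0.54 to -0.31, edgeR adjusted p = 0.0144, and without the line term log2 -0.67 with adjusted p = 0.1). Without a composition factor, by library totals, that log2 ratio was -0.06, so the Ogt transcript count was no check of the OGT-KO label; reads outside a deleted part of a gene, and reads from other liver cells, stay in such a count. Oga also fell in OGT-KO, from 1400 counts in control to 1023 (log2 -0.73, -0.84 to -0.61, edgeR adjusted p = 0.004, and by library totals log2 -0.36).

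The OGT-KO pair at 28 days addresses how the liver labelled as lacking OGT in hepatocytes differed from control at that time. Genes of fetal liver, extracellular matrix, bile duct cells, macrophages and cell division rose in OGT-KO, and genes of drug metabolism, lipid synthesis and male-biased expression fell. Afp, the fetal relative of albumin, had 132125 counts in OGT-KO and 82 in control (log2 10.35, 10.07 to 10.71, edgeR adjusted p = 8.33e-05), and Gpc3, a cell surface proteoglycan of fetal liver, had 7309 and 21 (log2 8.05, 7.55 to 8.86). Cyp2e1, among the most abundant control transcripts, fell from 199162 to 18225 counts (log2 -3.72, -3.75 to -3.70), and Hsd3b5, a male-biased steroid enzyme, from 4073 to 12 (log2 -8.44, -9.63 to -7.88). Alb itself fell less (log2 -0.51, edgeR adjusted p = 0.00934, and without the line term log2 -0.54 with adjusted p = 0.342, and by library totals log2 -0.14). Of 11803 genes with at least 1 CPM in either library, 3320 (28.1%) differed by at least 2-fold, 1937 higher and 1383 lower (58.3% higher). By library totals the same rule passed 2832 higher and 832 lower genes (77.3% higher), because that scaling moved the median log2 ratio of all genes by 0.369.

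**Figure D1:**
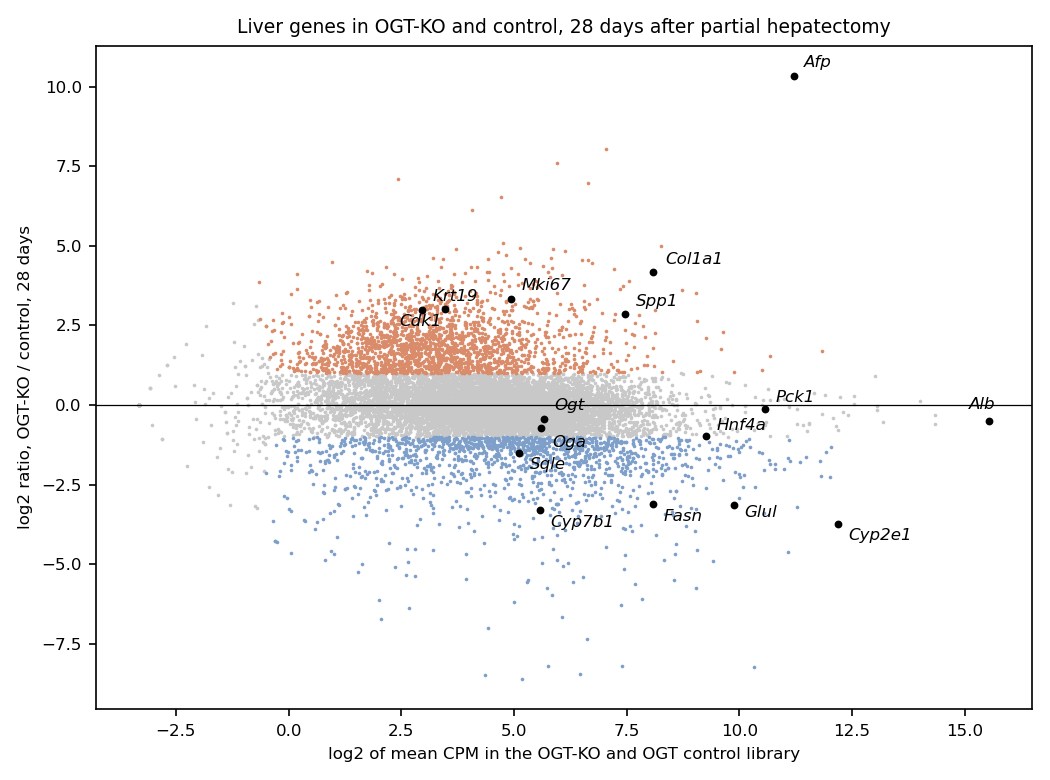
Log2 ratio of OGT-KO to control at 28 days (y axis) against log2 mean CPM of both libraries (x axis), 1 point per gene; orange and blue points are the 1937 higher and 1383 lower genes past the size rule, grey points the others, and black points named genes. Afp lies at 10.35, Col1a1 at 4.17 and Cyp2e1 at -3.72.

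Cell division genes were higher as a group in OGT-KO. For the list counts here and below the background was broad: of all 12026 genes tested by edgeR, 3134 rose and 3198 fell in OGT-KO. A split of risen and fallen members near those shares does not set a list apart. Of 18 mitosis genes, 17 rose by edgeR over all genes (adjusted over the list alone, 17 higher and 1 lower), with a median log2 of 2.57; Mki67 went from 125 to 1550 counts (3.34), Ube2c reached 3.61 and Prc1 3.59. Of 29 DNA replication genes, 23 rose and none fell (25 adjusted over the list alone, median 1.04), with Rrm2, a subunit of ribonucleotide reductase, at 2.55 and Lig1 at 2.31. Of 10 G1 cyclins and CDK inhibitors, 7 rose and 1 fell by either adjustment (median 0.84), including Ccnd1 (2.17) and the inhibitor Cdkn1a (1.79). Of 17 p53 targets, 10 rose and 2 fell by either adjustment (median 0.70), with Phlda3 at 3.48, and of 12 YAP targets 9 rose and none fell (10 adjusted over the list alone, median 1.68), with Ccn2 at 3.89 and Axl at 2.20. Of 20 growth factor and regeneration genes, 12 rose and 4 fell by either adjustment (median 1.12), with Tgfb3 at 3.57, Igfbp1 at 3.50 and Tgfb2 at 3.21. Of 14 glycolysis genes, 7 rose and 2 fell (7 and 4 adjusted over the list alone, median 0.43), with Pkm, the pyruvate kinase of proliferating cells, at 4.28 and Hk2 at 3.10. The medians of these 7 lists lay at or above percentile 99.4 of matched random lists.

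Markers of cells other than hepatocytes moved with OGT-KO, and moved unequally. Several lists were incomplete: rows were lacking for 8 of 17 listed recruited macrophage genes, among them Trem2, Gpnmb and Cx3cr1, and for 9 of 16 fetal genes. All 28 matrix and activated stellate cell genes rose (28 adjusted over the list alone, median 3.10), among them Loxl2 (4.48), Col5a2 (4.30) and Col1a1, which went from 654 to 14238 counts (4.17, 4.06 to 4.29). All 10 markers of quiescent stellate cells rose by either adjustment (median 1.65), with Hgf at 2.84. Of 13 cholangiocyte and progenitor markers 12 rose by either adjustment (median 2.88), with Cd24a at 4.59 and Krt19 at 3.00. Of 7 fetal and oncofetal genes 6 rose by either adjustment (median 3.14), with Cpe at 6.54 and Tspan8 at 3.14 beside Afp and Gpc3. Of 12 Kupffer cell markers 10 rose (median 1.89, Cd163 2.51, C1qb 2.46), and of 9 markers of recruited macrophages all 9 rose (median 2.71, Lpl 3.75, Lgals3 3.00), by either adjustment. Of 4 neutrophil genes 3 rose by either adjustment from low counts (median 2.80); S100a8 had 122 counts against 7. The 17 endothelial genes were split, with 5 rising and 5 falling by either adjustment and a median of 0.21 at percentile 91 (Stab1 1.99, Dnase1l3 -1.42). Of 6 erythroid genes 4 fell by either adjustment (median -0.57, percentile 4.59), led by Alas2 at -4.08; reads of the near-identical haemoglobin genes cannot be assigned with certainty.

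Hepatocyte genes were lower as groups in OGT-KO. Of 20 hepatocyte transcription factors 13 fell and none rose (median -0.85), with Cebpa at -2.21, Onecut1 at -2.15 and Hnf4a at -0.97 (edgeR adjusted p = 0.00154). Of 28 genes that HNF4A activates 23 fell and 2 rose (median -1.59), with Dio1 at -5.98 and Ugt2b1 at -4.88. Of 23 drug-metabolising P450 genes 22 fell (median -1.85), with Cyp1a2 at -5.73 and Cyp2f2 at -4.54; members of the Cyp2c family are near-identical and uncertain as single genes. Of 20 pericentral genes 16 fell (median -2.06), including Slc1a2 (-5.56) and Rgn (-4.09), while 20 periportal genes had 6 rising and 9 falling and a median of -0.34, which was 0.03 by library totals. Of 17 lipogenesis genes 16 fell (median -1.99, Thrsp -8.19, Scd1 -4.63), of 24 cholesterol synthesis genes 22 fell (median -1.77, Stard4 -3.55, Insig1 -3.52), and of 14 gluconeogenesis and glycogen genes 11 fell (median -1.66, Slc2a2 -3.40). Of 25 urea cycle and amino acid genes 22 fell (median -1.14, Glul -3.13); their percentile was 2.19, and 3.22 when members needed 5 CPM. The counts adjusted over the list alone were the same for each of these groups. With so many genes past the threshold over all genes, both adjustments were likely to give similar counts. Their agreement, here and for the other lists in OGT-KO, is therefore no separate support.

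Of 28 bile acid genes 20 fell and 2 rose in OGT-KO (3 higher adjusted over the list alone, median -0.87), with Slco1a1 at -4.86, Cyp8b1 at -4.70 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -1.56. Of 30 secreted liver proteins and clotting factors 25 fell and none rose (2 higher adjusted over the list alone, median -0.85), but abundant genes were lower in general and the percentile was 12.9; Apoa2 stood at -3.22 and Apoh at -2.35. Of 17 male-biased genes 16 fell (median -3.74, Cyp4a12a -6.28, Elovl3 -5.62) and of 9 female-biased genes 6 rose (median 1.49, Nipal1 6.14, Cyp2a4 2.86), by either adjustment. The Mup genes, whose copies are near-identical, held 0.0253% of counts in OGT-KO and 0.236% in control; Mup15, Mup17, Mup22 and Mup11 were among the lowest ratios, each at -7.01 or below. Car3 fell from 58692 to 236 counts (-8.22). Among the most abundant genes past the size rule, Cyp3a11 (-1.32), Serpina3k (-2.27), Ttr (-1.47) and Bhmt (-2.23) fell, and Clu (1.70), Apoa4 (1.55), Actb (1.10) and Itih2 (1.05) rose. S100a6 (6.99) and Mlph (5.09) were among the highest ratios, and Sema3e, at 296 counts against 0, was at least 81.6-fold higher.

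The edgeR fit called 3134 genes risen and 3198 fallen in OGT-KO, and 3207 of the 3320 genes past the size rule were among them. This test rests on the assumption that the lone OGT libraries vary like the OGA libraries; the DESeq2 Wald test called 2902 genes (1211 risen and 1691 fallen) and edgeR without the line term, added after the data were seen, 3035. Besides Ogt and Alb, the calls of Cyp7a1 (log2 -0.92, adjusted p = 0.445), Itih2 (0.51, 0.4), Apoa4 (2.55, 0.135), S100a8 (2.60, 0.0634), Lgals3 (4.07, 0.0587) and Sema3e (4.54, 0.0514) were lost without the line term, while their differences kept their direction. List members not named above lost calls too, among them Itgax (2.64) and Fabp5 (0.98) of the recruited macrophage list and Lrat (2.32) and Ngfr (1.54) of the quiescent stellate list. Among the erythroid genes Alas2 alone passed without the line term, and among the neutrophil genes Csf3r alone. The comparison of both controls at 28 days, given further on, passed 1230 genes by the same size rule.

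The OGA-KO pairs address the same question for the enzyme that removes O-GlcNAc, at 14 and 28 days. The differences were fewer. At 14 days 63 genes were at least 2-fold higher and 36 lower (0.839% of 11801 genes), and at 28 days 201 were higher and 103 lower (2.57% of 11851). At both times 12 genes were higher and 7 lower, where independent lists would share 0.65 and 0.244. Another 2 were higher at 14 days and lower at 28 days, and 1 the reverse, where such lists would share 0.381 and 0.416. These counts moved with the rule: at 5 CPM they were 27 at 14 days, 160 at 28 days and 6 at both times, and with a prior count of 10 those at 14 days and at both times were 48 and 7. Besides Oga, the genes 2-fold the same way at both times included Rgs16, a regulator of G protein signalling. It had 115 counts against 16 at 14 days (log2 2.57, 1.94 to 3.56) and 875 against 126 at 28 days (2.86, 2.61 to 3.16). The clock output gene Dbp (1.25 and 3.14) and Klf10 (1.23 and 1.04) were higher too. The immediate early gene Fos (-1.83 and -1.87), chosen after its values were seen, was lower. The edgeR fit over both times called 4 genes. Oga fell (log2 -2.48, adjusted p = 0.00617) and Rgs16 rose (log2 2.84, adjusted p = 0.0091), each the same way in 2 of 2 pairs. Neither passed without the line term or, without a day term, when either OGA control was left out, where edgeR called 0 genes, and Rgs16 did not pass in the 4 OGA libraries without the day term. Rgs16 also differed between the OGA controls, higher at 28 days by a log2 of 2.74. Ctrb1 (adjusted p = 0.0408) and Pnlip (adjusted p = 0.0485), digestive enzymes of the pancreas, were called on counts in the OGA-KO library at 28 days alone.

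**Figure D2:**
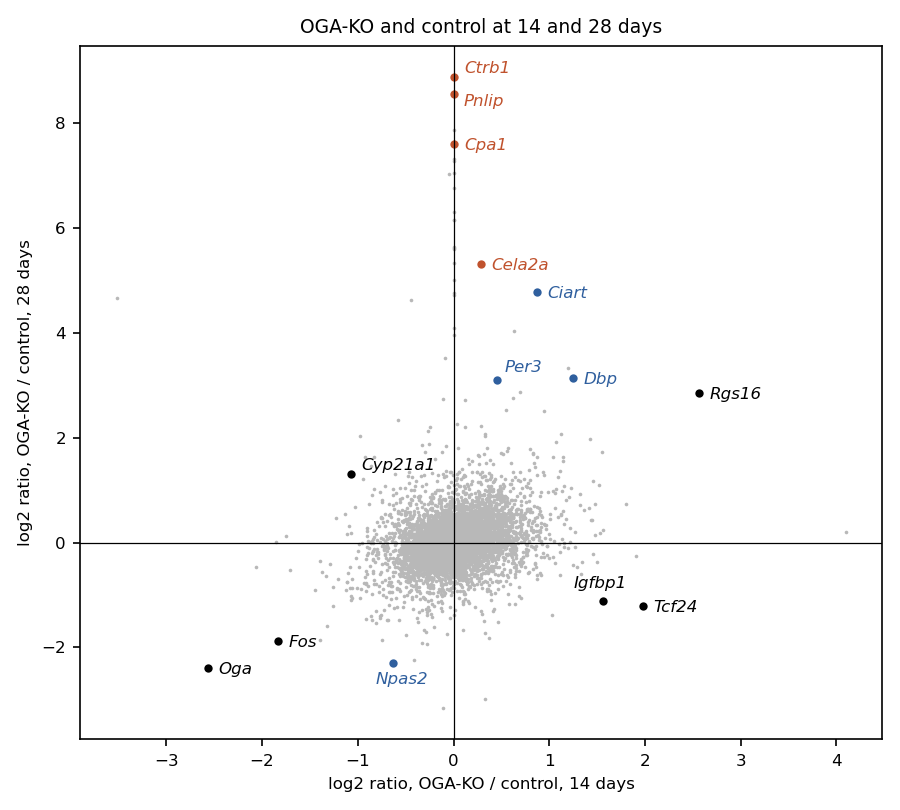
Log2 ratio of OGA-KO to control at 28 days (y axis) against 14 days (x axis), 1 point per gene; black points are named genes, blue points clock genes and orange points pancreas genes. Oga lies at -2.57 and -2.38, and the pancreas genes Ctrb1, Pnlip and Cpa1 are displaced along the 28 day axis alone.

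At 14 days in OGA-KO, markers of several cell types other than hepatocytes were slightly higher than in control. The 28 matrix genes had a median of 0.35 at percentile 100 (Col1a1 0.69, Col6a2 0.66), the 10 quiescent stellate markers 0.29 (Hand2 0.77) and the 13 cholangiocyte markers 0.46 (Bicc1 0.62, Spp1 0.59). The 17 endothelial genes (median 0.12, percentile 99.6) and the 6 erythroid genes (0.20, percentile 98.2) stood above too. The Kupffer cell (0.02), recruited macrophage (0.08) and neutrophil (-0.24) lists did not stand apart. The 25 fatty acid oxidation genes had a median of 0.15 at percentile 100 (Vnn1 1.06, Cyp4a10 0.91) and the 24 cholesterol synthesis genes -0.13 at percentile 0 (Dhcr7 -0.28). The 23 acute phase genes were lower (median -0.20, percentile 0), with Saa2 at -0.83 and Lcn2 at -0.83, and the 22 unfolded protein response genes too (median -0.16, percentile 0), with Sdf2l1 at -0.85 but Trib3 at 0.95. The 18 mitosis genes had a median of -0.27 at percentile 0.16, at low counts; Cdc20 had 45 counts against 66. Within these lists no gene passed edgeR over all genes. Among the 40 lists, 10 stood above and 7 below in this pair, the same numbers as between the OGA controls of 28 and 14 days. By the size rule 99 genes passed in this pair and 109 between those controls. Such list positions therefore do not separate an OGA-KO effect from differences between pools.

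At 28 days in OGA-KO, clock genes, female-biased genes and acute phase genes were among the groups that differed. Among the 40 lists, 12 stood above and 6 below, against 10 and 7 between the OGA controls of 28 and 14 days. The Kupffer cell (median 0.32), cholangiocyte (0.31), pericentral (0.24) and matrix (0.22) lists stood above, and the male-biased list (-0.14) below. Of 17 clock genes 8 were at least 2-fold higher and 4 lower, with Ciart at 4.78 (4.26 to 5.70), Dbp at 3.14 (3.00 to 3.29) and Per3 at 3.10 against Npas2 at -2.31; at 14 days Ciart was at 0.87 and Npas2 at -0.64. Of 9 female-biased genes 7 were 2-fold higher (median 1.27, percentile 100, Acot3 2.71, Nipal1 1.78, Cyp2a4 1.27); at 14 days their median was 0.32. Of 23 acute phase genes 6 were 2-fold higher (median 0.35, percentile 100, Orm3 1.87, Mt2 1.73, Lcn2 1.64), the reverse of the direction at 14 days, a difference that was not tested. The 4 neutrophil genes (median 0.98, percentile 99.4, 2 of them 2-fold higher) and the 5 adipose genes (median 0.55, percentile 99.8, 2 of them 2-fold higher) stood above as well, at low counts for S100a9 (37 against 17) and Cfd (46 against 8). The 22 unfolded protein response genes were again lower (median -0.24, Sdf2l1 -1.47, Derl3 -1.06), with Trib3 at 1.29. Single metabolic and growth genes also differed: G6pc1, the last enzyme of gluconeogenesis, -1.60, Cyp7a1 1.09, Cyp2a5 1.29, Ccnd1 1.64, Myc 2.20 and Igfbp1 -1.11. The 18 mitosis genes had a median of -0.43 at percentile 0, with Mki67 at 35 counts against 96. In the same library 9 of 11 pancreas genes had 136 to 904 counts with 0 in control; Ctrb1 was at least 319-fold and Pnlip at least 256-fold higher, and the list median was 7.04, or 6.48 with these genes at their bound. By edgeR adjusted over the list alone, 11 clock genes were higher and 4 lower across both times, as were 3 and 9 unfolded protein response genes and 1 and 1 acute phase gene. Higher by that adjustment were 4 female-biased genes, 4 matrix genes, 4 Kupffer cell genes and 10 pancreas genes. The 9 pancreas genes at 0 in control had 0 counts in both libraries at 14 days too. Any call of them rests on the OGA-KO library at 28 days alone and shows no effect across both times. The adjustment within a list did not cover the number of lists. Over all genes, none of the genes called by it passed except Ctrb1 and Pnlip.

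**Figure D3:**
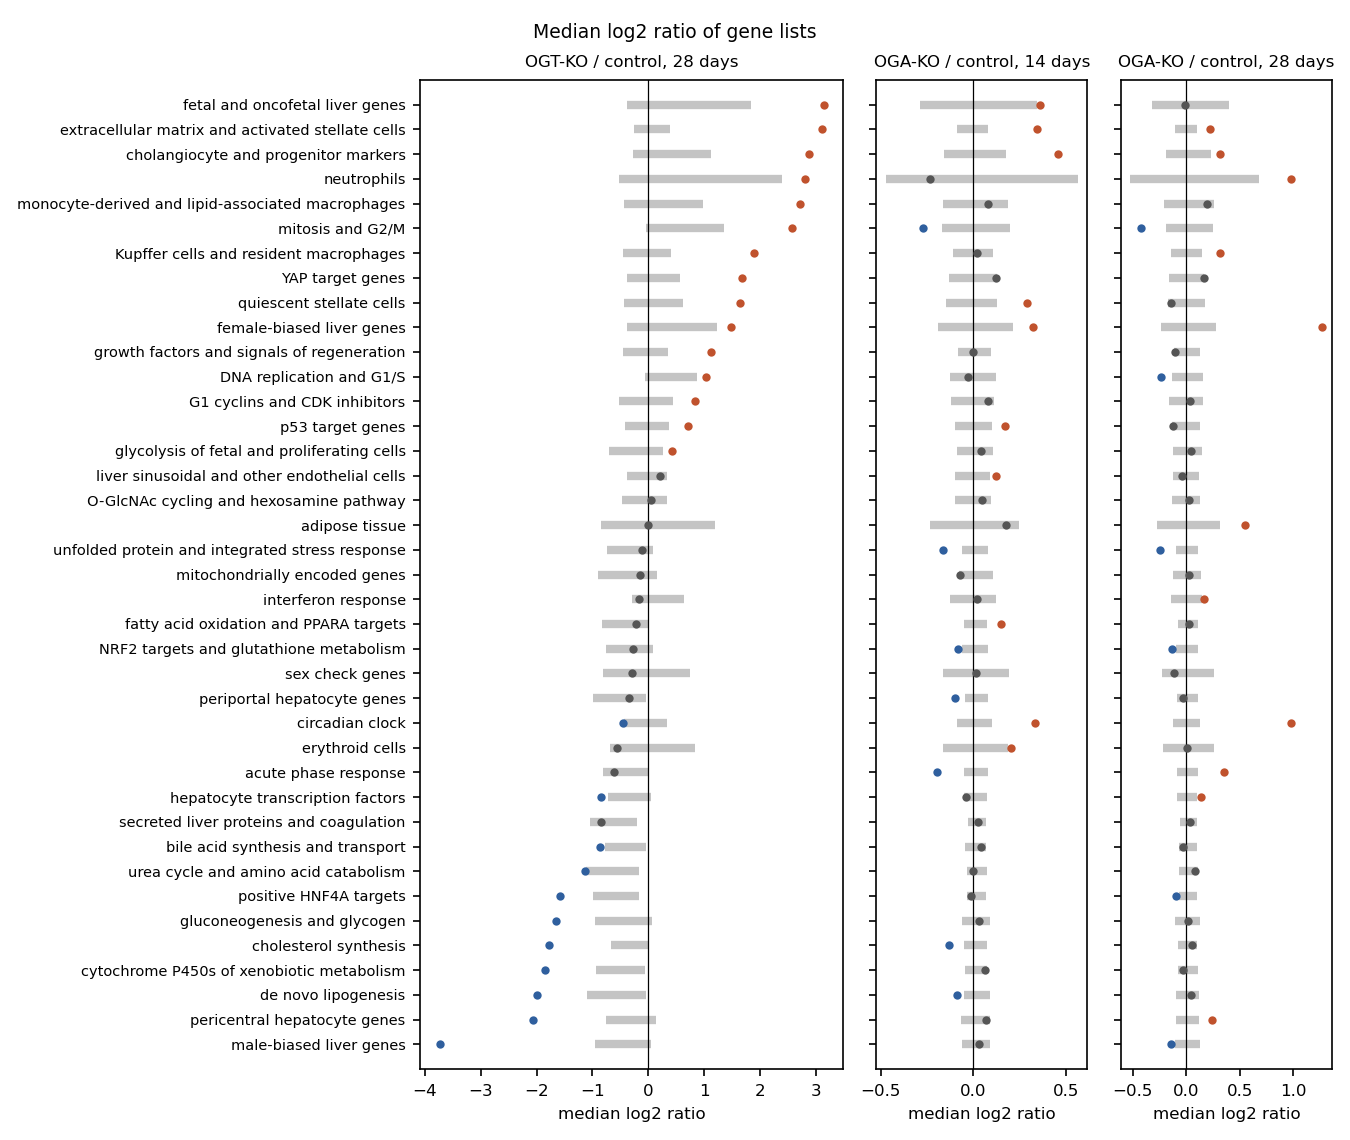
Median log2 ratio (x axes, with different ranges) of 39 gene lists, without the pancreas list, for OGT-KO at 28 days, OGA-KO at 14 days and OGA-KO at 28 days. Grey bars span the middle 95% of medians of matched random lists; orange and blue points lie above and below that range, dark grey points within it. The matrix list lies at 3.10 in OGT-KO and at 0.35 and 0.22 in OGA-KO.

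Among genes with at least 10 CPM that differed the same way at both times in OGA-KO, ranked by the smaller difference, the highest were Dbp, Klf10, Zbtb16 (1.32 and 0.92), Cyp4a10 (0.91 and 0.89), the glucocorticoid-induced Fkbp5 (0.87 and 1.64), Cyp4a14 (0.84 and 1.51), Gadd45g (0.83 and 1.70) and Tcim (0.76 and 1.08). Among the lowest besides Oga were Mup18, Mup1, Mup16 and Mup15, uncertain as single genes, Sdf2l1 and Fam222a (-0.81 and -1.31). Of these, Oga alone passed edgeR; the adjusted p of the others ran from 0.0742 for Cyp4a10 to 0.209 for Dbp. The edgeR count depended on the libraries and terms of the fit. With the 4 OGA libraries alone it was 2 with the day term and 1 without it. Without a day term, leaving out single libraries moved it further. By the DESeq2 Wald test it was 36.

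**Figure D4:**
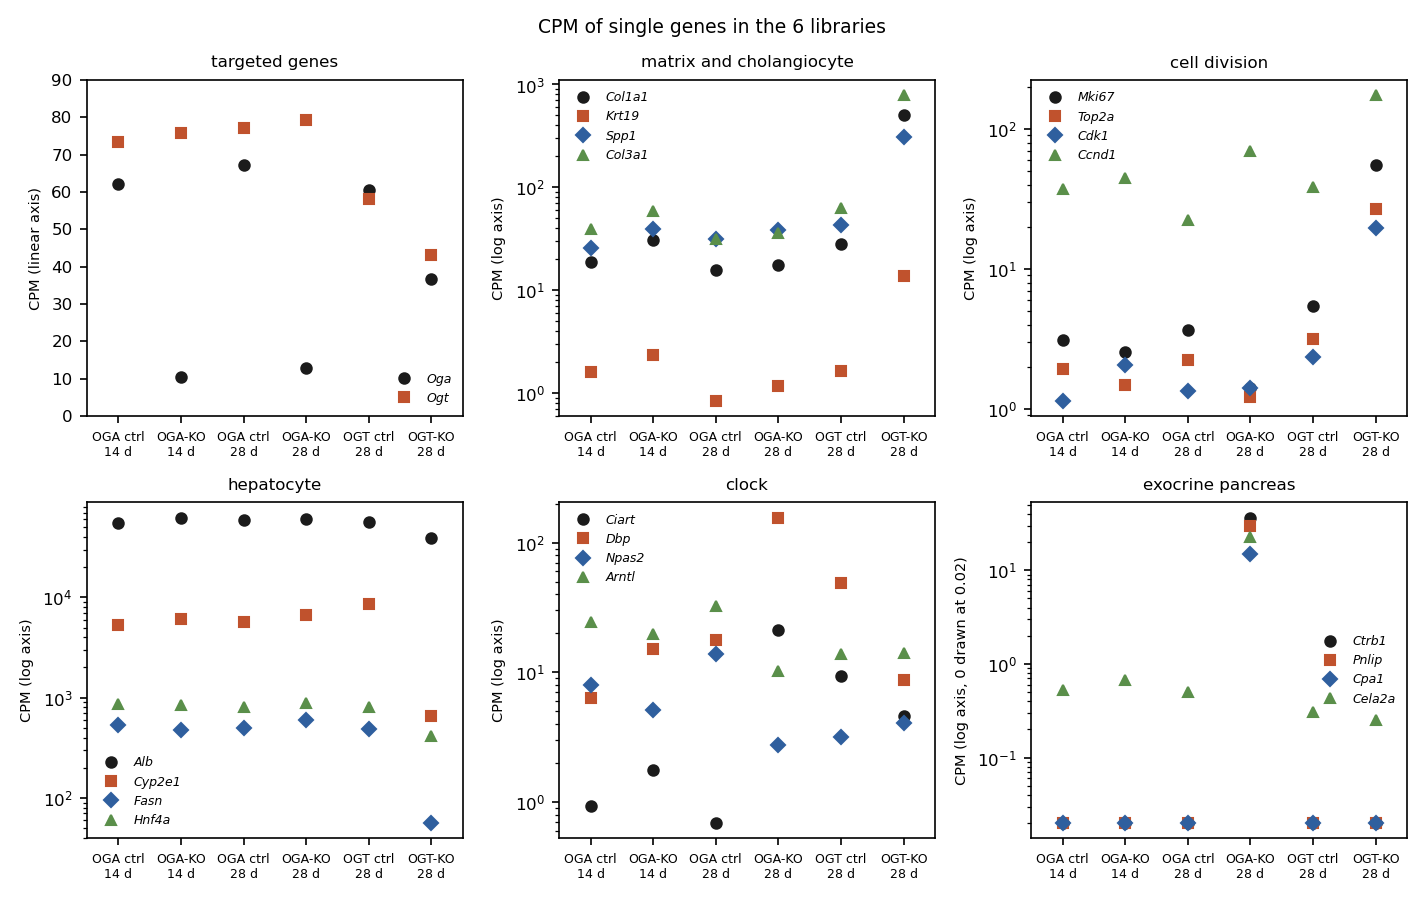
CPM of single genes in each of the 6 libraries, 1 point per library, on a linear axis for Oga and Ogt and on log axes for the other panels; a count of 0 is drawn at the bottom of the pancreas panel. Col1a1 lies at 510 CPM in OGT-KO and at 28.3 CPM in its control, and Ctrb1 at 36.6 CPM in OGA-KO at 28 days and 0 elsewhere.

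The fitted OGA-KO and OGT-KO effects differed, where OGA-KO was a mean over both times and OGT-KO was of 28 days alone. The OGT libraries added nothing to the spread of this fit. OGT deletion and the condition of 1 pool therefore cannot be told apart in a contrast of the OGA-KO and OGT-KO effects. The edgeR contrast between these effects called 5301 genes, 2570 more positive and 2731 more negative in OGT-KO; the DESeq2 Wald test called 2066 (720 and 1346) and edgeR without the line term 2766. Rgs16 rose in OGA-KO and fell in OGT-KO, from 2183 to 83 counts (log2 -4.96, -5.33 to -4.67, contrast adjusted p = 0.000158). Its OGT control was high, at 94.6 CPM against 4.81 in OGA control at 28 days and 0.653 at 14 days, and OGT-KO at 2.97 CPM lay between the OGA controls. Without the line term the log2 of Rgs16 in OGT-KO was -3.78 with an adjusted p of 0.25. Genes at least 2-fold higher in both OGT-KO and OGA-KO at 28 days numbered 78, where independent lists would share 24.9, and 18 were lower in both (10.7); 31 were higher in OGT-KO and lower in OGA-KO (14.3), and 26 the reverse (18.6). Across 11562 genes, which are not independent replicates, the fold changes of OGT-KO correlated with those of OGA-KO at 28 days with r of 0.127, and those of OGA-KO at both times with each other with r of 0.332.

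The pairs of 28 against 14 days address the course of time with and without OGA. Each time was 1 pool per genotype, so time cannot be told apart from the pool or the conditions of its collection. The 17 clock genes stood above in control (median 0.11, percentile 98.9) and in OGA-KO (0.57, percentile 100). In control livers 61 genes were at least 2-fold higher at 28 days and 48 lower (0.927% of 11758). Among genes with at least 10 CPM, as for the other rankings, Saa2, an acute phase protein, was the highest with 18362 counts against 2348 (2.87, 2.81 to 2.94), followed by Lrtm1 (1.98), Vnn1 (1.81), Igfbp1 (1.68) and Mup15 (1.65); the lowest were Mfsd2a (-1.77), Noct (-1.59), Pfkfb3 (-1.51), Camk2b (-1.48) and Mup9 (-1.41). The 28 matrix genes were lower at 28 days in control (median -0.20) and OGA-KO (median -0.18), as were the 6 erythroid genes (-0.71 and -0.84), the 24 cholesterol synthesis genes (-0.28 and -0.13) and the 17 interferon response genes (-0.23 and -0.18), all below the middle 95% of matched random lists. In OGA-KO 115 genes were higher at 28 days and 41 lower (1.32% of 11858), and without pancreas and clock genes 86 were higher and 41 lower. The highest of the named genes were the pancreas genes Ctrb1, Pnlip, Cel, Cpa1 and Cpb1, from at least 329-fold to at least 111-fold, and the lowest Mme (-1.30), Spon2 (-1.25), Cyp2c69 (-1.21), Pitx3 (-1.08) and Abtb2 (-1.04). The 23 acute phase genes had a median of 0.64 in OGA-KO and of -0.05 in control, where the mean was 0.21. Differences of the time course between genotypes were not tested.

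The controls of both lines at 28 days, which carry neither deletion, give a background for differences between pools, lines or batches. Here 556 genes were at least 2-fold higher in OGT control and 674 lower (10.4% of 11782, 45.2% higher, and 68.6% by library totals with 968 higher and 444 lower, where the median of all genes moved by 0.23). The highest were Rgs16 (4.27), Cyp4a14 (4.03), Nupr1 (3.59), Angptl8 (3.45) and Cdcp1 (3.35). Eno1b and Myom2 had 0 counts in OGT control and were at least 251-fold and at least 180-fold lower. Both had 0 counts in OGT-KO too. A difference of read assignment between the lines was not tested, so these bounds may not reflect expression. Serpina1e (-6.56) and Mup9 (-6.23), both with near-identical copies, and Ctse (-5.99, -9.96 to -5.04) followed. The 17 male-biased genes had a median of -1.26 with 10 at least 2-fold lower, the 24 cholesterol synthesis genes -0.93, the 23 acute phase genes -0.89, the 17 interferon response genes 0.85 with 8 at least 2-fold higher, and the 28 matrix genes 0.67. In this pair 13 of 40 lists stood above matched random lists and 8 below. The matrix, quiescent stellate, Kupffer cell, recruited macrophage, cholangiocyte, p53, P450, female-biased, male-biased and cholesterol lists stood apart the same way as in OGT-KO. The pericentral, lipogenesis, clock and neutrophil lists stood apart the opposite way. Line and batch cannot be told apart in this pair.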

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

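The tests of explanations in this part were chosen after the results were seen, so each explanation is a hypothesis weighed on the libraries that raised it. The edgeR contrast at the end was set before.

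Digestive enzyme genes appeared in the OGA-KO library at 28 days. There, 9 of the 11 pancreas genes had at least 20 counts with at most 3 in control, among them Ctrb1 (904 counts) and Pnlip (727). At 14 days the count of such genes was 0, which argues against an effect of OGA deletion present at both times. Pancreas tissue in the pooled RNA is a candidate explanation, but the count of 9 restates the observation that raised it and is no separate test. An effect of the deletion that starts after 14 days stays open and was not tested.

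Clock genes differed in the same library. Across the 17 clock genes, which are not independent replicates, Pearson's r with the difference between OGT control at 28 days and OGA control at 14 days, a pair without any deletion, was 0.806, and Ciart (3.21) and Dbp (2.93) were higher in that pair too. Pools collected at other times of day may therefore give this pattern. The r with the OGA-KO difference at 14 days was 0.853, so OGA deletion may also give it, and these data do not separate the explanations. The feeding state of the mice stays open too and was not tested; G6pc1 (-1.60) is a gene that responds to it.

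The OGT-KO difference was broad. Among the 10 pairs of libraries without OGT-KO, at most 1303 genes passed the size rule, against 3320 to 4102 in the 5 pairs with it, which argues against pool differences of the size seen between the other libraries. A lower share of hepatocytes as the whole cause would raise markers of the other cells alike. The medians of the matrix and endothelial lists differed by 2.89 (resampling interval 2.54 to 3.64). That interval covers the spread between listed genes and not between libraries. The matrix list also holds genes of activated stellate cells, which can rise without more cells. The quiescent stellate (1.65), Kupffer cell (1.89) and cholangiocyte (2.88) medians were higher too, so a changed mix of cells stays open. OGT deletion and the condition of this 1 pool cannot be told apart, and the Ogt log2 ratio of -0.43 did not settle whether the deletion took place. Rising Afp, Col1a1 and Mki67 may thus reflect loss of OGT, an unusual pool, or a mixture.

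The OGT-KO and OGA-KO effects differed by the edgeR contrast for 5301 of 12026 genes tested. Among these were 242 of the 330 named genes of the genotype comparisons, most of which were named for large ratios, so their higher share is no separate result. Across time in OGA-KO, 3 genes differed 2-fold in opposite directions: Igfbp1 (1.56 at 14 days and -1.11 at 28 days), Cyp21a1 (-1.07 and 1.30) and Tcf24 (1.98 and -1.20), of which Cyp21a1 and Tcf24 were chosen after their values were seen. The acute phase list had a median of -0.20 at 14 days and 0.35 at 28 days. In OGT-KO and OGA-KO at 28 days, 5 lists lay apart in opposite directions: mitosis, DNA replication, hepatocyte transcription factors, pericentral genes and clock genes. By library totals the clock median in OGT-KO was -0.08 in place of -0.45, still below random lists (percentile 1.89), and that of the transcription factors -0.48 in place of -0.85. In the same pair of comparisons 7 lists lay apart the same way, as did 7 in OGA-KO at both times. The differences over time and between lists were not tested. Outside the rows of the table, 158367 counts of the OGT-KO library could not be assigned to genes.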

How the results depend on the processing

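The fits without the line term, and counts without pancreas and clock genes or without Mup genes, were chosen after the data were seen, the other alternatives before. For OGA-KO at 14 days the 99 genes past the size rule became 48 with a prior count of 10, 27 at 5 CPM and 53 with the counting interval beyond 1.5-fold. At 28 days 304 became 160 at 5 CPM, and 269 without pancreas and clock genes (170 higher and 99 lower). For 28 against 14 days, control went from 109 genes to 45 at 5 CPM (71.1% higher, against 56%) and 71 with the interval, and OGA-KO from 156 to 73 at 5 CPM (89% higher, against 73.7%). Without pancreas and clock genes OGA-KO went to 127 (67.7% higher). The count at 5 CPM kept those genes. The 19 genes 2-fold the same way at both times became 7, 6 and 9 with the prior count of 10, 5 CPM and the interval. They became 18 without pancreas and clock genes. Without Mup genes, OGT-KO had 3303 genes past the size rule in place of 3320. Between both controls at 28 days it was 1212 in place of 1230. The 4 genes of the edgeR OGA-KO effect became 2 with DESeq2 size factors, 2 at 5 CPM, 2 with limma-trend, 36 by the DESeq2 Wald test, and 0 without the line term (259 with unadjusted p under 0.05). The 4 OGA libraries alone gave 2, and 1 without the day term. Without the day term, leaving out OGA-KO at 14 days gave 183, its control 0, OGA-KO at 28 days 8 and its control 0. The OGT-KO effect went from 6332 genes to 2902 by the DESeq2 Wald test and 3035 without the line term, and the contrast from 5301 to 2066 and 2766. The cause was not tested. Of 518 values of named genes, 131 moved beyond their counting interval by library totals and 129 in the authors' CPM, and 8 of 176 named genes of OGT-KO changed sign by library totals. Of list positions, 2 no longer stood apart at 5 CPM: urea cycle genes in OGT-KO (percentile 3.22) and interferon genes in OGA-KO at 28 days (97.3). In 6 cases a list came to stand apart: pancreas genes in OGT-KO by library totals and at 5 CPM, YAP targets in OGA-KO at 28 days by library totals and with a prior count of 0.5, and in OGA-KO at 14 days mitochondrially encoded genes by library totals and adipose genes at 5 CPM.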

Other observations

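The genes in the next paragraph were chosen after their values were seen, and no test was added for them.

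Outside the lists, single genes also differed in OGT-KO. S100a11 (4.55), Anxa2 (2.99), the hyaluronan receptor Cd44 (3.08) and the TWEAK receptor Tnfrsf12a (3.35) were higher than in control, as were the epithelial keratins Krt8 (1.75) and Krt18 (2.10). The carboxylesterases Ces3b (-6.67) and Ces1c (-2.93), Adh1 (-3.40), Akr1c6 (-2.85) and the complement genes C9 (-3.26), C8a (-3.18) and C8b (-3.47) were lower.

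In OGT-KO 15 of 40 lists lay above and 11 below matched random lists, against 13 and 8 between the controls of both lines at 28 days. Such numbers do not by themselves separate an OGT-KO effect from differences between pools or lines. The other 14 lists did not stand apart in OGT-KO. Of the latter, 7 changed the sign of their median by library totals: the NRF2 targets (-0.27 to 0.10), periportal genes, fatty acid oxidation genes (-0.22 to 0.15), unfolded protein response genes (-0.12 to 0.25), interferon response genes (-0.17 to 0.20), mitochondrially encoded genes (-0.15 to 0.22) and sex check genes (-0.30 to 0.08). For NRF2, fatty acid oxidation and interferon genes the mean (0.11, 0.16 and 0.09) also differed in sign from the median. The 23 acute phase genes had a median of -0.62 and the 14 O-GlcNAc and hexosamine genes of 0.05, neither apart, and the 17 clock genes of -0.45 at percentile 2.29.

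In rows with 0 counts in both OGT libraries, 13 genes had at least 20 counts in each OGA library, among them Eno1b (894, 505, 624 and 855) and Myom2 (382, 474, 503 and 611). A difference of strain, line or read assignment between the OGT and OGA libraries was not tested.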
